A study of Homo sapiens with 14 samples.

How the data were processed

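MCF7, an estrogen receptor-positive human breast cancer cell line, carried an overexpressed PAPP-A (gene PAPPA), a secreted protease that frees insulin-like growth factors from their binding proteins. The cells were grown in 3D in Matrigel for 48 h with 10% serum from lactating (Lac) or non-lactating (NL) women, with 500 to 700 colonies in each culture. Xenografts were established in nude mice for 10 days, the mice were then injected with Lac or NL serum, and tumors were collected after 28 days. Per the labels' protocols, snap-frozen material gave poly(A) RNA for sequencing. There were 3 NL and 3 Lac culture libraries, and 4 NL and 4 Lac xenograft libraries. The labels do not say whether replicates stand for separate serum donors or separate cultures of 1 serum pool. Nor do they say whether each xenograft library came from a separate mouse. Each library has its own name and batch label there, which the labels do not explain.

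The deposited tables hold log10 values, per the values themselves: 10 to the power of each value, minus 1, summed to 1e+06 in each column, so that the unit is log10(CPM + 1). The aligner, the counting tool and the genome build are not given in the sources used here, nor is any handling of mouse reads. The culture table has 177816 transcripts under RefSeq accessions. The xenograft table has 35238 genes under symbols, of which 28 were turned into dates by a spreadsheet and were left out; they held at most 0.236% of CPM in a library.

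CPM were recovered from both tables. In the cultures, 95.6% of transcripts were matched to a gene symbol and summed to 41582 genes; the unmatched transcripts held 1.17% to 1.36% of CPM. In the xenografts, 1172 names were replaced by a current symbol for matching with lists and annotation, and the deposited name is printed. Each library's depth was read from the CPM step of 1 read. In the xenografts 100% of values above 0 were whole reads within 0.01 reads. In the cultures 13.9% to 16.9% were, as reads shared out between transcripts in fractions would give, which was not tested.

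Neither table holds counts as deposited, so the test planned for such values was used: limma 3.58.1 (R 4.3.3; eBayes with a mean trend, robust off) on log2(CPM + 1), Lac minus NL, within each setting. Fold changes are on that scale, which understates the change of genes near or under 1 CPM. Genes needed at least 10 reads at the median depth (0.747 CPM in cultures, 0.760 CPM in xenografts) in as many libraries as the smaller group, and 15 reads in all. P-values are adjusted by Benjamini-Hochberg over the genes of a setting, and genes with an adjusted p under 0.05 are called. The p-values measure only the spread between the libraries. If replicates share a serum pool, they say nothing about spread between donors. If xenografts share a mouse, the p-values treat libraries as independent that are not.

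Lists were 56 sets of genes fixed before the data were examined, as were the tests, the groups and the rule for named genes; 50 lists in cultures and 53 in xenografts had at least 5 tested genes. They were tested with limma's camera at its preset inter-gene correlation of 0.01, 2-sided, adjusted over the lists of a setting. Camera with a correlation estimated for each list, and fry, were run as alternatives. The difference between settings was, per gene, the difference of both effects over the root of their summed squared standard errors, with a normal p adjusted over 13193 genes.

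The rule for named genes took, in each setting, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM, no overlap between the groups and a plain gene symbol. Where fewer than 10 genes were called, it took the 10 with the smallest p instead. It also took up to 4 members with the smallest p of each list described, and PAPPA, IGF1R, IGFBP4, IGFBP5, ESR1, PGR, PRLR, SNAI1, DDR2 and MKI67. RNA classes, KRAS and the genes that moved with it, and the genes whose effects differed between settings were added after the data were seen.

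The fits were tested on simulated counts with the real means and depths. Genes changed on purpose had a mean of at least 5 CPM. Noise was drawn for each gene on its own, at the spread of the real fit, with counting error added once more. The simulation therefore held no variation shared between genes, and its counts are only a rough guide to the real libraries. For cultures, over 18689 genes, 32 of 59 genes changed 1.5-fold were called, 63 of 74 changed 2-fold, and 67 of 67 changed 4-fold, with 9 unchanged genes called. For xenografts, over 16966 genes, the counts were 0 of 58, 7 of 70 and 38 of 72, with 3 unchanged genes called. For the difference between settings, over 13248 genes, the normal p called 100 unchanged genes and a t distribution called 14.

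Alternatives were relative log expression (RLE) and TMM factors computed from their formulas, no filter, a minimum mean of 5 CPM, limma-voom, a replicate block, a pseudocount of 0.1, protein-coding genes only, libraries thinned to equal reads, covariates, single libraries left out, and transcripts not summed. The whole reads of the xenografts were also given a quasi-Poisson test written in R, with dispersions squeezed to their trend by limma, and all 4 groups 1 limma fit with an interaction. In another, each library's trend on GC content and transcript length was removed. GC and length were known for 77.5% of tested culture genes, too few, so that fit used coding genes, of which 95.1% had both. Shares of reads have exact Clopper-Pearson 95% intervals no wider than 0.0306 percentage points on either side. These intervals, and the limit of 3 reads that a count of 0 allows, cover counting error only, since PCR copies are not independent molecules. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.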

Results

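RNA from PAPP-A-overexpressing MCF7 cells was sequenced after exposure to serum from lactating (Lac) or non-lactating (NL) women, in 3D cultures (3 NL and 3 Lac libraries) and in mouse xenografts (4 NL and 4 Lac libraries). The series title asks whether breastfeeding acts on tumors through a metabolic vulnerability, and both comparisons here are Lac minus NL. Depth is given in units of 1e+06 reads (M). In cultures, NL libraries 1, 2 and 3 held 23.6, 19.6 and 21.2 M reads and Lac libraries 1, 2 and 3 held 7.11, 7.22 and 6.17 M reads. Depth therefore followed serum in the cultures, and a batch marked by depth cannot be told apart from serum there. In xenografts, NL libraries 1 to 4 held 13.1, 10.0, 13.4 and 13.2 M reads and Lac libraries 1 to 4 held 13.6, 9.71, 10.6 and 14.1 M reads. Gene values below are mean CPM ± SD, with n = 3 per group in cultures and n = 4 per group in xenografts, and log2 fold changes carry their standard error (SE).

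The culture comparison asks what 48 h of lactation serum does to tumor cells with no host. The largest fall was LRRC8B, a subunit of the volume-regulated anion channel, from 10.4 ± 2.22 CPM in NL to 1.12 ± 1.22 CPM in Lac cultures (log2 fold change −2.58, SE 0.34, adjusted p 0.00307). DPYSL3 and CRMP1, collapsin response mediators that steer axons, went from 3.39 ± 1.14 to 0.658 ± 0.434 CPM and from 3.07 ± 0.577 to 0.703 ± 0.724 CPM. The microtubule regulator STMN2 (−1.25, SE 0.30), the tubulin TUBB2B (−1.20, SE 0.24), the membrane glycoprotein GPM6A (−1.25, SE 0.30) and the spectrin anchor ANK2 (−1.32, SE 0.22) also fell. MEF2C, a transcription factor of muscle and neurons, fell from 3.69 ± 1.18 to 0.634 ± 0.714 CPM, and the ciliary gene CFAP263 from 3.52 ± 1.13 to 0.691 ± 1.20 CPM. MIR3648-1, transcribed from ribosomal DNA, fell from 35.9 ± 7.41 to 15.1 ± 1.76 CPM.

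The largest rise in cultures was HPS5, which serves the biogenesis of lysosome-related organelles, from 8.73 ± 4.10 to 23.3 ± 7.0 CPM (log2 fold change 1.36, SE 0.25, adjusted p 0.0109). PIGN, an enzyme of GPI-anchor synthesis that also guards chromosome stability, rose from 30.3 ± 8.67 to 67.1 ± 5.0 CPM. CCDC192, a little-studied coiled-coil gene, rose from 20.3 ± 2.06 to 42.1 ± 6.32 CPM. MIR12136, whose sequence lies in mitochondrial DNA, rose from 96.8 ± 28.1 to 233 ± 42.3 CPM. PSD3, an activator of the small GTPase ARF6, rose by 0.98 (SE 0.26), and MIR421 by 0.98 (SE 0.26). Both lost their call under RLE factors, with adjusted p 0.0715 and 0.0696, and over all alternatives theirs ranged from 0.00896 to 0.262 and from 0.0110 to 0.194. The rises of COMMD3-BMI1 (1.13, SE 0.21), ATP6V1G2-DDX39B (1.06, SE 0.18), NPIPB11 (0.98, SE 0.15) and POTEB3 (1.14, SE 0.23) are uncertain, since these readthrough or multicopy genes share sequence with neighbours or copies. The small RNAs share sequence with longer transcripts.

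**Figure D1:**
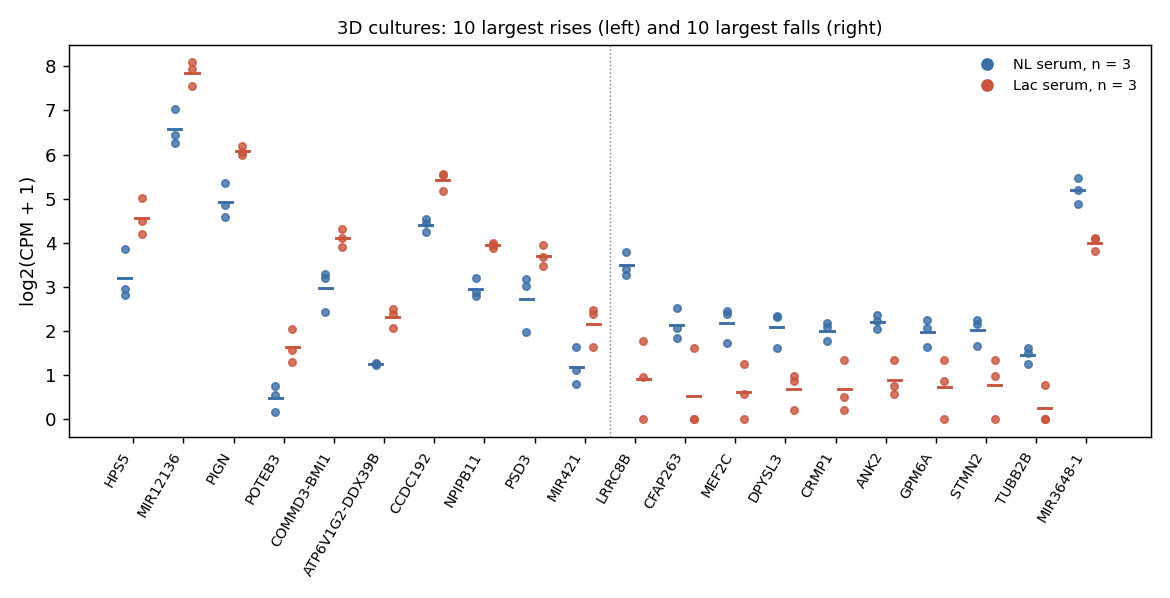
Level of the 10 largest rises and 10 largest falls in each 3D culture library, in log2(CPM + 1), with a point per library and a bar at the mean of 3. LRRC8B lies lower in each of the 3 Lac libraries than in any NL library, with a log2 fold change of −2.58.

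Of 18586 genes tested in cultures, limma called 1004, of which 890 were higher and 114 lower in Lac, and 4370 had an unadjusted p under 0.05. In each called gene every Lac library lay beyond every NL library. Over all tested genes 28.99% had such separate groups, against 10% by chance. The median log2 fold change of all genes was 0.11, and RLE factors, which remove that shift, gave 381 higher and 363 lower genes, 495 of them among the 1004. TMM factors gave 378 higher and 315 lower. Relative to the shift, HPS5 was at 1.25 and LRRC8B at −2.69. The count was 291, 376 and 398 without NL replicate 1, 2 or 3, and 1678, 272 and 274 without Lac replicate 1, 2 or 3. Most of the 38 called named genes lost their call in at least 1 alternative fit. Only PIGN, CCDC192, NPIPB11, MIR3648-1, GAP43 and ATP5F1D kept an adjusted p under 0.05 in each alternative fit that tested them.

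The rises were concentrated in noncoding genes. Of 4146 long noncoding RNAs, 430 were called higher and 1 lower, with a median log2 fold change of 0.34 (0.26 under RLE factors). Of 13723 coding genes, 407 were called higher and 107 lower, with a median of 0.06, and under RLE factors 135 were higher and 354 lower, with a median of −0.06. Long noncoding RNAs held 2.31% to 2.44% of reads in NL and 3.19% to 3.72% in Lac libraries. Coding genes moved with base composition. A fit of coding genes alone called 283, 225 higher and 58 lower, of which 240 had a known GC content and length. In that fit the lowest of 5 groups by GC content had a median log2 fold change of 0.15 with 66 called higher and 2 lower, and the highest −0.09 with 1 called higher and 26 lower. The same gradient ran through the xenografts, from 0.09 to −0.17. By transcript length, medians went from −0.02 in the shortest of 5 groups to 0.15 in the longest in cultures, and from −0.26 to 0.16 in xenografts. With each library corrected for GC content and length, 40 of these 240 coding genes were still called, among them LRRC8B, PIGN, CCDC192, NPIPB11, DPYSL3, ANK2, GAP43, ATP5F1D and UQCRFS1 of those named here.

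**Figure D2:**
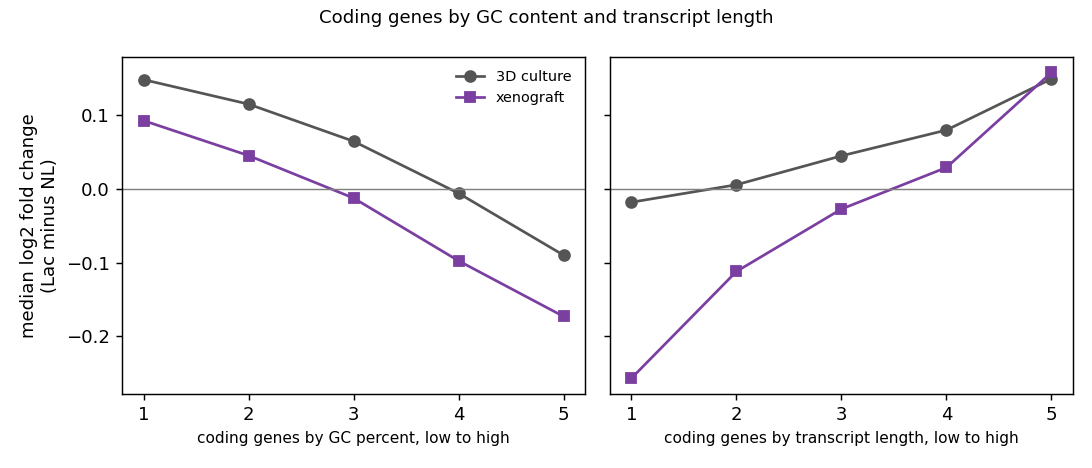
Median log2 fold change (Lac minus NL) of coding genes in 5 equal groups by GC percent (left) and by transcript length (right), for cultures (grey circles) and xenografts (purple squares). Culture medians run from 0.15 in the lowest GC group to −0.09 in the highest.

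The genes of the PAPP-A and hormone axes did not pass the threshold in cultures. PAPPA itself stood at 595 ± 76.1 CPM in NL and 530 ± 14.99 CPM in Lac cultures (adjusted p 0.315). IGF1R, the receptor for the growth factors that PAPP-A frees, came closest, at 228 ± 25.6 against 285 ± 19.2 CPM (log2 fold change 0.32, SE 0.09, adjusted p 0.0551; 0.19 and 0.228 under RLE factors, with adjusted p from 0.0356 to 0.348 over all alternatives). IGFBP4, the binding protein PAPP-A cleaves, was at 199 ± 46.2 and 160 ± 43.0 CPM, and IGFBP5 at 1077 ± 246 and 1013 ± 161 CPM. The estrogen receptor gene ESR1 had a log2 fold change of 0.36 (SE 0.14, adjusted p 0.152, from 0.0155 to 0.523 over all alternatives), its target PGR 0.06 (SE 0.29) and the prolactin receptor PRLR 0.22 (SE 0.08). SNAI1 (−0.20, SE 0.28) and DDR2 (−0.15, SE 0.26), which mark a mesenchymal and collagen-sensing state, lay under 2 CPM. The proliferation marker MKI67 was at 610 ± 77.9 and 706 ± 19.2 CPM (adjusted p 0.182).

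Genes of central carbon metabolism were lower as lists in Lac cultures, by small amounts. Pyruvate carboxylase (PC), which feeds the TCA cycle with oxaloacetate, fell from 34.3 ± 3.6 to 22.2 ± 4.43 CPM (log2 fold change −0.61, SE 0.13, adjusted p 0.0232, from 0.00313 to 0.111 over all alternatives). In all, 21 of 28 TCA cycle genes were lower. OGDH (−0.21), IDH2 (−0.26) and SUCLG1 (−0.16) were lower without passing the threshold. The list median was −0.15 relative to all genes, with an adjusted p of 0.00260 (adjusted p = 0.342 with an estimated correlation), and 1 gene was called over all genes and 1 adjusted over the list alone. Of 24 genes of cholesterol synthesis 19 were lower, among them EBP (−0.30, SE 0.10), TM7SF2 (−0.33, SE 0.12) and MVD (−0.23, SE 0.10), while the rate-limiting HMGCR was not (0.17, SE 0.09). EBP was called under RLE factors (adjusted p 0.0401, from 0.0401 to 0.258 over all alternatives), and TM7SF2 ranged from 0.0323 to 0.514. That list had a relative median of −0.19 and an adjusted p of 0.000410 (adjusted p = 0.342 with an estimated correlation), with 0 genes called over all genes and 0 adjusted over the list alone, where EBP had the smallest unadjusted p. In the creatine and polyamine list, creatine kinase CKB fell by 0.34 (SE 0.09, adjusted p 0.0415, from 0.0192 to 0.272 over all alternatives). GAMT (−0.45, SE 0.13) and SRM (−0.34, SE 0.12) did not pass over all genes. Over all alternatives the adjusted p of SRM ranged from 0.0205 to 0.411 and that of GAMT from 0.0289, under RLE factors, to 0.238. Its adjusted p was 0.000511 (adjusted p = 0.337 with an estimated correlation), with 1 gene called over all genes and 2 adjusted over the list alone. For glycolysis, with ALDOA (−0.25), PGAM1 (−0.18) and SLC2A1 (−0.24) lower and PFKFB3 (0.27) higher, the adjusted p was 0.00333 (adjusted p = 0.342 with an estimated correlation). In the pentose phosphate list, PGLS fell from 25.5 ± 0.426 to 18.8 ± 1.56 CPM, and G6PD, its first enzyme, was at −0.25 (SE 0.09). The list had an adjusted p of 0.0182 (adjusted p = 0.342 with an estimated correlation) and lost its call with coding genes alone as the background (adjusted p 0.0823).

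Respiratory chain subunits moved both ways in cultures. The ATP synthase subunit ATP5F1D fell from 95.7 ± 3.36 to 64.2 ± 5.02 CPM and the complex III subunit UQCRFS1 by 0.29 (SE 0.07, adjusted p 0.0397). ATP5F1E (0.37, SE 0.08), COX7C (0.41, SE 0.09) and the complex I subunit NDUFB1 (0.76, SE 0.17) rose, of which ATP5F1E and COX7C lost their call under RLE factors (adjusted p 0.101 and 0.0928; from 0.0114 to 0.184 and from 0.00830 to 0.187 over all alternatives). Among cytosolic ribosomal proteins RPL18A fell by 0.46 (SE 0.10), and RPS24 (0.40, SE 0.08) and RPL37 (0.33, SE 0.08) rose, both without a call under RLE factors (adjusted p 0.0704 and 0.174; from 0.00665 to 0.132 and from 0.0134 to 0.443 over all alternatives). The ribosomal and respiratory lists were not called, with adjusted p 0.0932, 0.113 for complex I and 0.152 for complexes III to V. Under RLE factors all 3 were called lower (adjusted p 0.0103, 0.0160 and 0.0206), and with coding genes alone none was (0.657, 0.635 and 0.774).

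Neuronal, myeloid and immediate-early genes formed the strongest lists in cultures, by adjusted p in the main fit. GAP43, which drives axon growth, fell from 1.37 ± 0.330 to 0.0469 ± 0.0812 CPM (log2 fold change −1.17, SE 0.19, adjusted p 0.00666). SYP, a synaptic vesicle protein, was at 1.15 ± 0.187 and 0.520 ± 0.342 CPM, and 7 of 8 genes of the neuronal list were lower (adjusted p 0.000144; adjusted p = 0.337 with an estimated correlation). GAP43 and STMN2 were its 2 genes called over all genes and its 2 adjusted over the list alone. The 6 myeloid genes tested were all lower, among them the receptor CSF3R (5.25 ± 1.94 against 2.40 ± 0.809 CPM), lysozyme LYZ (6.64 ± 2.06 against 3.98 ± 0.811 CPM), S100A9 (−0.37) and PTPRC (−0.46). That list had an adjusted p of 0.000159 (adjusted p = 0.337 with an estimated correlation), with 0 genes called over all genes and 3 adjusted over the list alone; CSF3R had the smallest unadjusted p, 0.00330, in limma, and was called under RLE factors (adjusted p 0.0439, from 0.0231 to 0.200 over all alternatives). Whether the RNA of these myeloid genes came from the tumor cells was not tested. Of 24 immediate-early genes 18 were lower, with DUSP1 (−0.42, SE 0.13), JUND (−0.29), JUNB (−0.26) and NR4A1 (−0.26) in front (adjusted p 0.000126; adjusted p = 0.321 with an estimated correlation). DUSP1, JUND and JUNB were called under RLE factors (adjusted p 0.0380, 0.0426 and 0.0397; from 0.0376 to 0.198, from 0.0363 to 0.662 and from 0.0397 to 0.565 over all alternatives).

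Single genes of other lists also passed in cultures. CEBPB, a transcription factor of mammary development and stress, fell from 54.7 ± 8.25 to 35.7 ± 4.70 CPM, and the chaperone HSPB1 from 1115 ± 121 to 822 ± 5.75 CPM. Their adjusted p ranged from 0.00896 to 0.147 and from 0.00615 to 0.218 over all alternatives. The luminal factor SPDEF fell from 324 ± 27.7 to 251 ± 11.5 CPM (log2 fold change −0.36, SE 0.08, adjusted p 0.0270). The replication licensing factor CDT1 fell by 0.36 (SE 0.09, adjusted p from 0.0192 to 0.264 over all alternatives). The clamp loader RFC3 rose by 0.35 (SE 0.08) and lost its call under RLE factors (adjusted p 0.149, from 0.0189 to 0.225 over all alternatives). XAF1, an interferon-induced antagonist of XIAP, rose from 4.91 ± 0.785 to 9.84 ± 1.35 CPM. In the antigen presentation list the invariant chain CD74 (−0.80, SE 0.24) and its activator CIITA (0.58, SE 0.17) went opposite ways, not called over all genes in limma but called when adjusted over the list alone (1 higher, 1 lower). Over all alternatives their adjusted p over all genes ranged from 0.0157 to 0.238 and from 0.0323 to 0.251. IGFBP2 (−0.37, SE 0.11), the lipogenic enzyme FASN (−0.24, SE 0.11), the keratin KRT8 (−0.27, SE 0.11) and the estrogen receptor corepressor NRIP1 (0.46, SE 0.12, adjusted p 0.0508) did not pass. IGFBP2 was called under RLE factors (adjusted p 0.0283), and over all alternatives the adjusted p ranged from 0.0117 to 0.214 for IGFBP2, 0.0883 to 0.528 for FASN, 0.0269 to 0.398 for KRT8 and 0.00347 to 0.437 for NRIP1.

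Camera called 24 of 50 lists lower and 0 higher in cultures. The 16 called lists not described above covered antigen presentation, lysosomes, epithelial adhesion, the mitochondrial ribosome, fatty acid synthesis and oxidation, stress responses through ATF4 and heat shock, mesenchymal genes, glucocorticoid targets, S phase, luminal markers, estrogen targets, iron, glutamine transport and MYC targets. Their medians were −0.11 to −0.24 relative to all genes, and their adjusted p = 0.337 to 0.667 with an estimated correlation. The MYC target list was called lower with a median of 0.00 before the shift of all genes was taken off. With an estimated correlation camera called 0 lists, the smallest adjusted p being 0.321. RLE factors called 30 lists lower, the 24 and 6 more: cytosolic ribosomal proteins, complex I, complexes III to V, nucleotide synthesis, the NRF2 response and the unfolded protein response. With coding genes alone as the background, 11 of the 24 kept their call. The 13 that lost it, with adjusted p from 0.0674 to 0.351, were S phase, the ATF4 response, heat shock, mesenchymal genes, estrogen and glucocorticoid targets, luminal markers, fatty acid oxidation, pentose phosphate, iron, glutamine transport, the mitochondrial ribosome and MYC targets. With each of the 6 libraries left out in turn, 9 lists kept their call in 6 of 6 fits: neuronal, myeloid, immediate-early, cholesterol, creatine, TCA cycle, glycolysis, lysosome and epithelial adhesion. The other 15 kept it in 3 to 5 of 6, with adjusted p up to 0.713. After correction for GC content and length, 4 lists were called: the neuronal, myeloid, cholesterol synthesis and TCA cycle lists, with adjusted p 0.00699, 0.00699, 0.0116 and 0.00699.

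The xenograft libraries differed widely within serum groups. Across genes, r was 0.927 to 0.983 between NL libraries, 0.836 to 0.975 between Lac libraries and 0.883 to 0.973 between libraries of different serum. KRAS, an oncogene held at 44.4 to 56.3 CPM in cultures, ranged over 1094-fold in xenografts, from 53.3 CPM in Lac library 1 to 58381 CPM in NL library 2, where it took 5.84% of reads (95% interval 5.82% to 5.85%). The islet hormones insulin (INS) and glucagon (GCG) and the heme enzyme ALAS2 ran with KRAS: INS reached 113 CPM in NL library 2 and was at 0 in Lac library 1, which allows up to 0.220 CPM. The 13 mitochondrial mRNAs took 3.41% to 22.4% of reads in Lac and 5.99% to 11.4% in NL libraries. Neither KRAS (2-sided exact permutation p 0.514) nor the mitochondrial share (p 0.943) separated the serum groups, where the smallest p that 4 against 4 allows is 0.0286. The first principal component held 62.8% of the variance. Over the 8 libraries it correlated with the log2 mitochondrial CPM (r 0.956, rho 0.929) and with depth (r −0.951, rho −0.929), with exact permutation p of 0.000248 and 0.00223, and of 0.00109 and 0.00223. Adjusted over 4 such relations the p for r were 0.000992 and 0.00218, and r was 0.930 and −0.935 without the 2 libraries farthest from the median. KRAS had r 0.768 and rho 0.881 (exact permutation p 0.00427 and 0.00724, adjusted p 0.00569, r 0.839 without the 2 farthest), and the ribosomal protein sum r 0.325 and rho 0.429 (exact permutation p 0.438 and 0.299, adjusted p 0.438, r 0.366 without the 2 farthest).

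**Figure D3:**
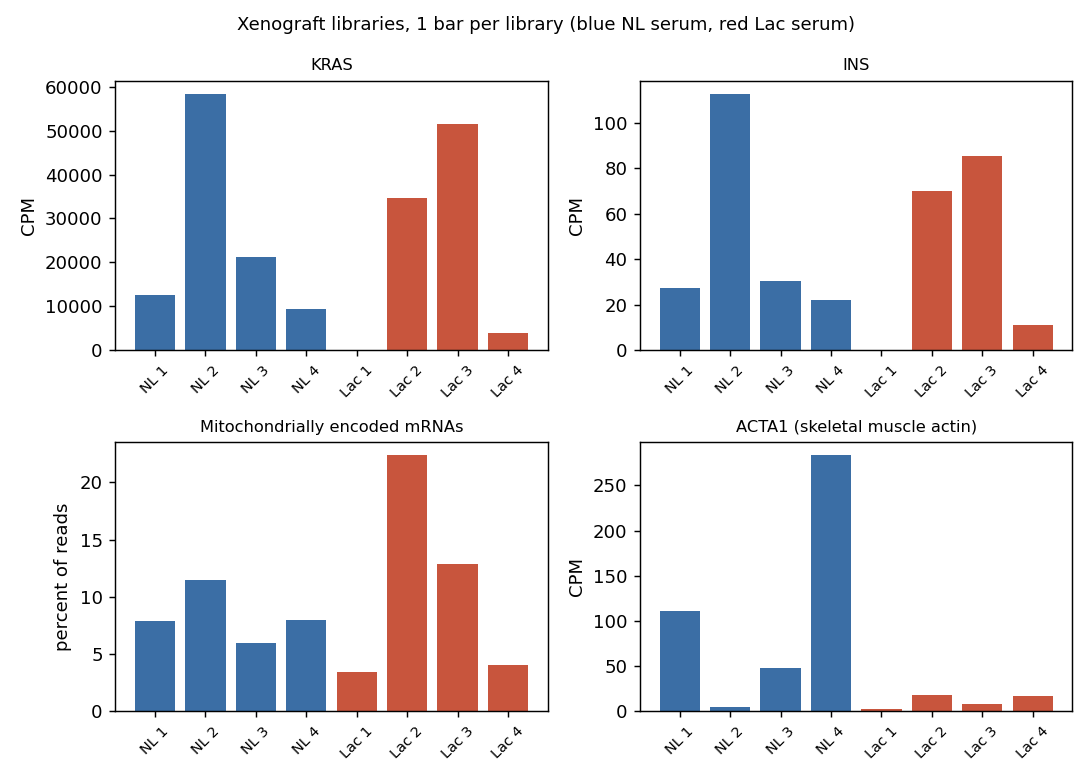
KRAS and INS in CPM, the share of reads from mitochondrially encoded mRNAs in percent, and the muscle actin ACTA1 in CPM, with a bar for each xenograft library (NL blue, Lac red). KRAS runs from 53.3 CPM in Lac library 1 to 58381 CPM in NL library 2, and both serum groups hold high and low libraries.

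The xenograft comparison asks what lactation serum given to the host does to the tumors. The handling of mouse reads is not given, so host reads may be counted under human symbols, which was not tested. The xenograft values, those of the fibroblast, matrix, skin, muscle and inflammatory lists included, therefore cannot be assigned to the tumor cells alone. No single gene passed. The smallest p belonged to AMPD1, the AMP deaminase of skeletal muscle, at 6.07 ± 3.93 CPM in NL and 1.05 ± 0.595 CPM in Lac tumors (log2 fold change −1.70, SE 0.40, adjusted p 1.00). The retinoid-binding CRABP1 stood at 6.41 ± 2.70 and 1.91 ± 0.683 CPM, and the mitochondrial phosphatase PTPMT1, needed for cardiolipin, at 46.3 ± 7.73 and 26.3 ± 3.03 CPM. MINOS1, a part of the cristae-organizing MICOS complex, was at 91.5 ± 12.3 and 57.2 ± 2.27 CPM, and COPS9, of the COP9 signalosome, at 53.8 ± 5.63 and 30.9 ± 5.98 CPM. The glucocorticoid receptor NR3C1 was on the higher side, at 25.8 ± 5.74 in NL and 50.8 ± 12.5 CPM in Lac, as was the actin-binding CALD1, at 19.0 ± 4.25 and 38.9 ± 8.83 CPM. The other genes so chosen were GNG13 (−0.96, SE 0.25), HAPLN3 (−1.15, SE 0.31) and SPDYE2B (1.06, SE 0.28), the last uncertain because it has near-identical copies.

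Of 16586 genes tested in xenografts, limma called 0, and 635 had an unadjusted p under 0.05 (192 higher and 443 lower). Limma-voom, RLE factors and TMM factors also gave 0, as did a quasi-Poisson test on whole reads (761 at an unadjusted p under 0.05). The groups did not overlap in 578 genes, or 3.48%, against 2.86% by chance. The count was 1 without NL replicate 2. Median SE was 0.12 in cultures and 0.31 in xenografts, and in the simulation 7 of 70 genes changed 2-fold were called. That simulation held no variation shared between genes, unlike these libraries, so it is only a rough guide. Changes of this size could well have been missed.

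PAPPA was at 214 ± 88.5 CPM in NL and 206 ± 118 CPM in Lac tumors, with a log2 fold change of −0.09 (SE 0.41). IGFBP4 averaged lower in Lac, at 337 ± 133 against 206 ± 77.7 CPM (−0.70, SE 0.35), and IGFBP5 higher, at 64.5 ± 35.0 against 143 ± 148 CPM. IGF1R (−0.20, SE 0.32), ESR1 (0.23, SE 0.78), PGR (−0.71, SE 0.62), PRLR (−0.24, SE 0.55), SNAI1 (0.38, SE 0.30), DDR2 (0.72, SE 0.46) and MKI67 (0.28, SE 0.30) differed by less than or little more than their spread. All had an adjusted p of 1.00.

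Energy and protein-making genes were lower as lists in Lac xenografts. Of 57 cytosolic ribosomal proteins 56 were lower, as RPS16 (740 ± 164 against 447 ± 55.8 CPM), RPS23 (676 ± 164 against 422 ± 54.7 CPM) and RPL30 (726 ± 152 against 452 ± 98.0 CPM). Of 36 subunits of respiratory complexes III to V 35 were lower, among them the ATP synthase subunit ATP5L (128 ± 16.2 against 79.7 ± 15.1 CPM), COX7C (−0.77, SE 0.24) and UQCR10 (−0.62, SE 0.20). Complex I followed with 36 of 38, led by NDUFC1 (37.3 ± 2.75 against 23.6 ± 3.94 CPM) and NDUFA6, and the mitochondrial ribosome with 38 of 40, led by MRPS34 and MRPL11 (−0.70, SE 0.23, and −0.65, SE 0.23). Relative to all genes the list medians were −0.36, −0.42, −0.37 and −0.32. Their adjusted p were 1.24e-13, 5.22e-12, 1.16e-09 and 3.10e-08, and each had adjusted p = 0.639 with an estimated correlation. Each list had 0 genes called over all genes and 0 adjusted over the list alone in limma, with the smallest unadjusted p 0.0122 (RPS16), 0.00674 (ATP5L), 0.00977 (NDUFC1) and 0.0126 (MRPS34). For comparison, the shortest of 5 groups of coding genes by transcript length had a median log2 fold change of −0.26 in xenografts.

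Carbon metabolism, S phase and estrogen targets were lower as well. Of 28 TCA cycle genes 25 were lower, with IDH2 at 162 ± 32.9 against 107 ± 15.7 CPM (adjusted p 0.0267; adjusted p = 0.877 with an estimated correlation). Of 25 glycolytic genes 21 were lower, with ALDOA at 2719 ± 531 against 1795 ± 654 CPM and the hypoxia-induced PFKFB4 at 73.4 ± 20.8 against 45.7 ± 29.6 CPM (adjusted p 0.0284; adjusted p = 0.877 with an estimated correlation). In the creatine, polyamine and urea list, spermine synthase SMS was at 263 ± 44.5 against 173 ± 58.0 CPM and the arginase ARG2 at 5.33 ± 0.717 against 2.94 ± 1.69 CPM (adjusted p 0.0143; adjusted p = 0.639 with an estimated correlation). The S phase genes GINS2 (−0.67, SE 0.26), E2F1 (−0.56, SE 0.23) and CDT1 (−0.56, SE 0.26) were among 27 of 30 lower (adjusted p 0.000374; adjusted p = 0.873 with an estimated correlation). TFF1, a secreted estrogen target, was at 1006 ± 172 against 697 ± 140 CPM, RARA at 130 ± 9.23 against 97.3 ± 16.2 CPM and SUSD3 at 7.69 ± 3.64 against 3.67 ± 2.13 CPM. They were among 24 of 30 estrogen targets that were lower (adjusted p 0.00648; adjusted p = 0.873 with an estimated correlation). The widest gap was in the skin and muscle list, at a median of −2.35, and lay in its muscle genes: creatine kinase CKM was at 40.7 ± 53.8 against 2.56 ± 3.13 CPM, ACTA1 at 112 ± 122 against 11.4 ± 7.43 CPM, TNNT3 at 67.2 ± 81.7 against 5.61 ± 5.48 CPM and DES at 77.3 ± 56.9 against 12.7 ± 15.2 CPM. That list had an adjusted p of 0.000871 (adjusted p = 0.639 with an estimated correlation), and its summed level did not separate the groups (2-sided exact permutation p 0.114).

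Interferon and inflammatory genes were higher as lists in Lac xenografts. Of 28 interferon-stimulated genes 22 were higher, among them the antiviral MX1 (10.4 ± 2.92 against 16.0 ± 4.90 CPM), OAS2 (3.48 ± 2.24 against 5.66 ± 1.20 CPM), IFI6 (0.89, SE 0.48) and DTX3L (0.72, SE 0.34), with adjusted p 0.000374 (adjusted p = 0.639 with an estimated correlation). These genes were not high in the same Lac libraries. IFI6 was at 107 and 132 CPM in Lac libraries 1 and 4, and at 31.7 and 35.7 CPM in 2 and 3. MX1 was at 11.3 and 12.3 CPM in 1 and 4, and at 19.5 and 20.9 CPM in 2 and 3. DTX3L went with IFI6, and TNFAIP2 of the NF-kB targets below went with MX1, while OAS2 and LCN2 did not split this way. Of 17 NF-kB targets 16 were higher, such as TNFAIP2 (0.61, SE 0.35) and LCN2 (0.71, SE 0.55), with adjusted p 0.00395 (adjusted p = 0.639 with an estimated correlation). The FOXO targets INSR, IRS2 and ERBB3, which insulin signalling represses, were at 46.9 ± 12.9 against 62.6 ± 11.3, 35.8 ± 11.9 against 46.5 ± 2.55 and 402 ± 64.8 against 554 ± 183 CPM. They were among 12 of 16 higher (adjusted p 0.0217; adjusted p = 0.877 with an estimated correlation). The LXR targets MYLIP (0.81, SE 0.26) and the cholesterol exporter ABCA1 (1.03, SE 0.43) were among 6 of 8 higher (adjusted p 0.0464; adjusted p = 0.873 with an estimated correlation). The matrix genes COL6A2 (0.47, SE 0.23) and COL5A2 (0.66, SE 0.38) were among 23 of 30 collagen and matrix genes (adjusted p 0.0246; adjusted p = 0.877 with an estimated correlation). DCN (0.57, SE 0.26) and PDGFRA (0.86, SE 0.67) were among 10 of 13 fibroblast markers (adjusted p 0.0413; adjusted p = 0.877 with an estimated correlation), and the androgen-regulated UGT2B15 (0.89, SE 0.48) was among 9 of 11 thyroid hormone and androgen targets (adjusted p 0.0284; adjusted p = 0.808 with an estimated correlation). The LXR and fibroblast lists lost their call under RLE factors (adjusted p 0.0623 and 0.0649). After correction for GC content and length the fibroblast, collagen and matrix, and creatine, polyamine and urea lists lost theirs (adjusted p 0.0603, 0.0804 and 0.184).

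Camera called 10 lists lower and 7 higher of 53 in xenografts, and 0 with an estimated correlation, where the smallest adjusted p was 0.639. All 17 kept their call with coding genes alone as the background. The count was 11 without Lac replicate 4 (2 higher, 9 lower), 15 without NL replicate 2 (3 higher, 12 lower) and 21 without Lac replicate 1 (4 higher, 17 lower). Lac library 1 was richest in transcripts of skin (KRT1 at 44.8 CPM, against 1.44 at most in the others) and NL library 4 in those of muscle (ACTA1 at 283 CPM, against 111 at most). NL libraries 1 and 3 also held muscle transcripts, with ACTA1 at 111 and 48.4 CPM. ACTA1 was at 4.38 CPM in NL library 2 and at 17.9 CPM at most in Lac libraries. Without Lac library 1 and NL library 4, the count was 3 higher and 18 lower. The skin and muscle list was still lower there (camera adjusted p 0.00589), so that this fit does not remove the muscle difference. With each of the 8 libraries left out in turn, the interferon and NF-kB lists kept their call in 8 of 8 fits, with adjusted p from 1.12e-05 to 0.0172 and from 7.24e-06 to 0.0486. Leaving out 1 library does not remove the split of Lac libraries 1 and 4 from 2 and 3, which lay at opposite ends of the first component. The other 5 higher lists kept it in 4 or 5 of 8, with adjusted p up to 0.949. Of the lower lists, glycolysis kept its call in 3 of 8 fits (adjusted p up to 0.420), the TCA cycle in 4 (0.438), estrogen targets in 6 (0.137), creatine, polyamine and urea in 6 (0.0653) and skin and muscle in 7 (0.0577). The ribosomal, respiratory, mitochondrial ribosome and S phase lists kept theirs in 8 of 8, with adjusted p up to 0.0265. Without Lac library 1 and NL library 4 the NF-kB list alone of the 7 kept its call, and the interferon list had adjusted p 0.0516. With the mitochondrial share as a covariate the count was 4 higher and 11 lower. The thyroid hormone and androgen, LXR and fibroblast lists then lost their call (camera adjusted p 0.0795, 0.139 and 0.0545). Over the called lists, 0 genes were called over all genes and 0 adjusted over the list alone.

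**Figure D4:**
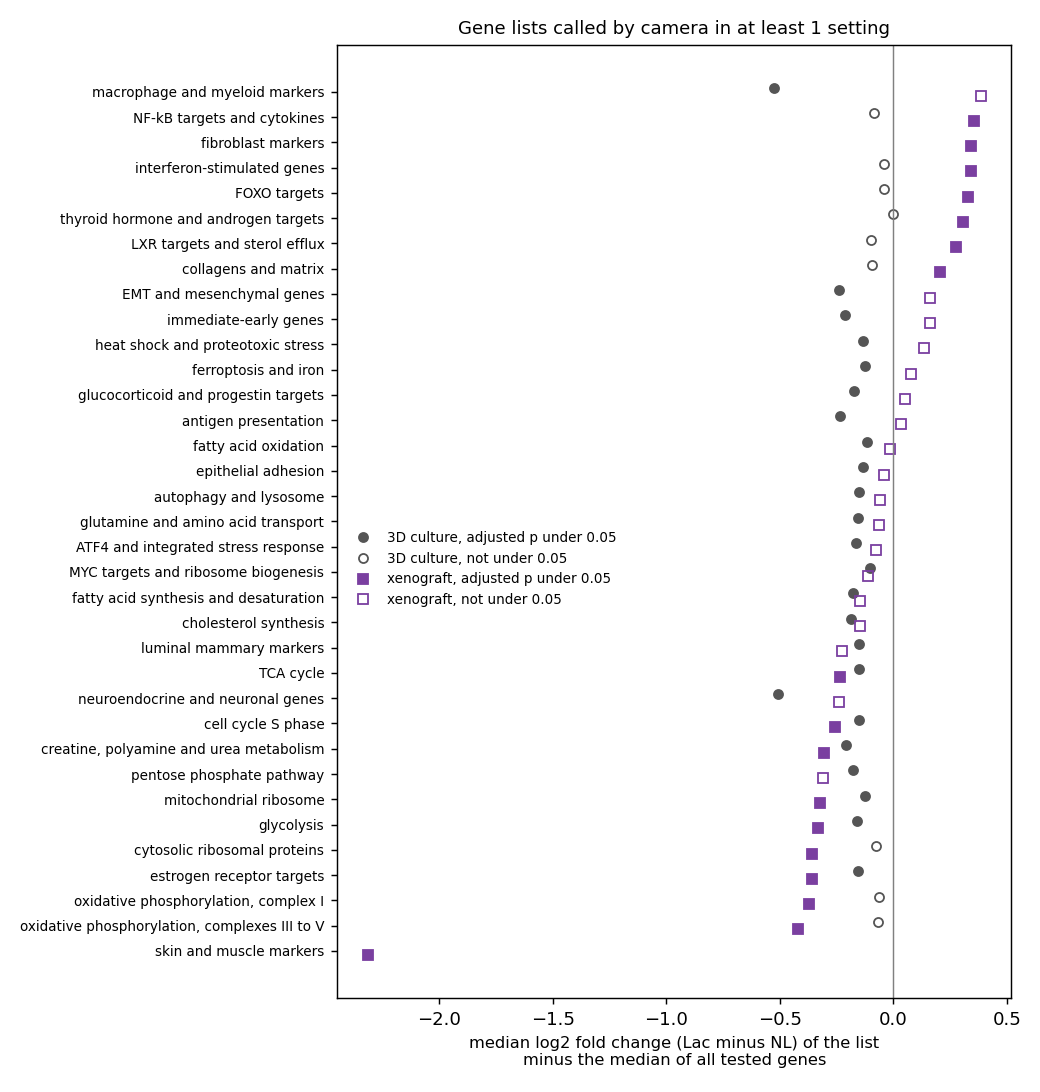
Median log2 fold change (Lac minus NL) of each list called in at least 1 setting, minus the median of all tested genes, for cultures (grey circles) and xenografts (purple squares), filled where the adjusted p was under 0.05. Skin and muscle markers lie lowest in xenografts, at −2.31, and no list was called higher in cultures.

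Effects that differed between cultures and xenografts were sought next. LRRC8B, which fell in cultures, had a log2 fold change of 0.14 (SE 0.26) in xenografts, a difference of 2.72 (SE 0.43, adjusted p 2.48e-06). DPYSL3 differed by 2.13, the receptor kinase GRK5 by 1.81 and the immune adaptor LCP2 by 1.54, all with estimates below 0 in cultures and above 0 in xenografts. On the other side, COX7C (−1.19), ATP5F1E (−0.88), MICOS10 (−0.96; MINOS1 in the xenograft table) and the ubiquitin ligase subunit RBX1 (−0.96) had estimates above 0 in cultures and below 0 in xenografts, as had the meiotic repair gene MSH5 (−1.11), AMPD1 (−1.86) and LOC102724594 (−1.45). No gene was called in xenografts, so the test shows a difference of effects and not opposite changes in both settings. ZNG1F (−1.32) and GTF2IP13 (−1.19) belong to families of near-identical copies and are uncertain. These 13 genes, 4 up and 9 down, were called of 13193, with 684 at an unadjusted p under 0.05. The balance depended on the scaling: RLE factors called 8, 6 up and 2 down, and TMM factors 7, 5 up and 2 down. With a t distribution 1 was called, LRRC8B, and 1 limma fit of all 4 groups with an interaction called 0. The count was 2, 23, 5 and 5 without xenograft NL replicate 1, 2, 3 or 4, 44 and 8 without xenograft Lac replicate 1 or 2, and 20 without culture Lac replicate 1.

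The direction of change was then compared between settings. Of 461 genes called in cultures and tested in both settings, 326 (70.7%) had the same direction in xenografts (2-sided exact binomial p 2.68e-19, although genes are not independent replicates). Of 360 genes higher in Lac cultures 243 (67.5%) were also higher in xenografts, where 44.7% of all shared genes were, and of 101 lower genes 83 (82.2%) were also lower. With RLE factors the share was 79.2%. In coding genes with GC content and length corrected in both settings it was 59.8%, against 71.1% before in the same 418 genes. Of lists called lower, 6 were shared: S phase, creatine and polyamine, estrogen targets, glycolysis, mitochondrial ribosome and TCA cycle. Of these, S phase and the mitochondrial ribosome kept their xenograft call with any 1 library left out. Each kept its culture call in 4 of 6 such fits and lost it with coding genes alone (adjusted p 0.135 and 0.0823). With an estimated correlation 0 lists were called in either setting. Independence gives 4.41 (hypergeometric p 0.211, over 49 lists that share genes).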

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

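Of the tests below, those on thinned libraries, on the first component without KRAS, on the GC-corrected agreement and on regrouped libraries were written before their values were seen. Those on neuronal markers, on GC content and length in coding genes, on depth as a batch, on islet genes and on KRAS against serum were chosen after the result was seen.

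Several xenograft values lay far from the other 3 of their group. CRABP1 was at 2.93 CPM in Lac library 3 (next 1.71), COPS9 at 62.2 CPM in NL library 2 (next 51.4) and MINOS1 at 60.6 CPM in Lac library 3 (next 56.3). PAPPA was at 380.2 CPM in Lac library 4 (next 164), DDR2 at 8.97 CPM in NL library 4 (next 3.09) and DES at 35.4 CPM in Lac library 4 (next 7.31). PDGFRA was at 22.3 CPM in Lac library 1 (next 3.59), ARG2 as low as 0.412 CPM in Lac library 2 (next 3.77), and NL library 2 had 10.0 M reads (next 13.1). Chance puts about 1 in 20 groups of 4 this far, or 6.40 of the 128 groups examined, and 9 were found.

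A test of the difference between settings called 13 genes. With a t distribution it called 1, and 1 fit of all 4 groups called 0. On simulated counts the normal p called 100 unchanged genes of 13248 and the t distribution 14. Xenograft minus culture, the log2 fold change differed by 2.72 for LRRC8B, 2.13 for DPYSL3, 1.81 for GRK5 and 1.54 for LCP2. It differed by −1.11 for MSH5, −1.45 for LOC102724594, −1.19 for COX7C, −0.96 for MICOS10, −0.96 for RBX1, −0.88 for ATP5F1E, −1.19 for GTF2IP13, −1.86 for AMPD1 and −1.32 for ZNG1F. Chance was not excluded: 17 of 100 drawn splits gave as many genes as the real 13, the highest of the others giving 4407, which points to a structure of the libraries other than serum.

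Some genes known from neurons, such as GAP43, STMN2, DPYSL3 and CRMP1, were lower in Lac cultures. With libraries thinned to equal depth, the median log2 fold change of the 19 low coding falls was −1.11, against −1.17 before. Thinning keeps each gene's expected CPM, so it weighs only the added counting error of fewer reads, which does not account for the falls. It cannot test an effect of depth before reads were counted, which remains open. Of these 19 genes, 12 still passed the filter after thinning and 9 were still called. RNA from neuron-like cells in the NL cultures may contribute. The 10 neuronal markers tested and not called had a relative median of −0.28, between what that predicts and what it excludes. That value cannot decide, since the 4 markers called lower were left out of it by their own change. The most abundant of the 10, TUBA1A, was at 104 CPM in NL and 81.5 CPM in Lac, and KIF5C, SYT1 and MAP1B were at similar levels with either serum. The last ones stood at 33.2, 29.9 and 73.9 CPM in NL, so a small amount of neuron-like RNA would not show in them. Of the 10, 8 were lower in Lac, and DCX and SYN1, at relative log2 fold changes of −0.96 and −0.85, were lower in every Lac library than in any NL library. Of all 20 markers listed, 10 were lower in every Lac library, and 6 of the 20 were not tested. NEFM and INA, among those lower, averaged 0.0925 and 0.127 CPM in NL and 0 CPM in Lac. In Lac libraries 1 read stood for 0.138 to 0.162 CPM, so depth alone could give that. Over all tested genes 28.99% had separate groups, in either direction. An effect of serum on these genes of the tumor cells remains open, since a preparation batch may follow serum, as depth does (ratio 2.71).

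In Lac cultures long noncoding RNAs were higher and GC-rich coding genes lower. The gap of long noncoding over coding genes was 0.30 after thinning and 0.28 before, so added counting error does not account for the first part. Since thinning keeps each gene's expected CPM, an effect of depth before reads were counted remains open. With GC content and length corrected in the coding part, the median size of the called changes was 0.45, against 0.53 before, with the median SE at 0.0936 and 0.105. These genes were picked for large changes, while medians by GC content ran only from 0.15 to −0.09. That size could therefore not have fallen by much, and it does not weigh GC content and length as a cause. Calls went from 240 to 40, so that 40 genes stayed called with both corrected. Genes at an unadjusted p under 0.05 went from 2587 to 1706. After correction 99 of the 240 had an unadjusted p within the largest p called before, 0.00103. The direction shared with xenografts may rest on GC content and length in part, with agreement at 59.8% after correction. A preparation batch that follows serum could give the same picture, since the lowest NL depth was 2.71 times the highest Lac depth.

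KRAS, INS, GCG and ALAS2 split the xenograft libraries. KRAS did not separate the serum groups (2-sided exact permutation p 0.514), but a part for serum cannot be excluded with 4 libraries in each. Pancreatic islet cells do not account for INS and GCG, since IAPP, TTR and CHGB together reached 1.06% of INS in the library highest in INS. Counts taken from other genes by KRAS and mitochondrial reads do not account for the split, since scores on the first component with and without these genes correlated at 0.9997 across 8 libraries. A source outside the tumors, such as reads of another library, is a candidate that was not tested.

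Chance was weighed for the main results by regrouping the libraries. In cultures the real split gave 1004 genes and the highest other 66, and 24 lists against 23; with 10 splits a share under 0.05 cannot be reached, the real split being 1 of 10 in each case. In xenografts the count of genes tests nothing, since the real split called 0 and all 35 of 35 splits give at least that. For lists chance was not excluded: 11 of 35 gave at least 17, with 30 at most. The split of NL libraries 1 and 2 with Lac libraries 2 and 3 from the rest gave 5263 genes, which points to a structure of the libraries other than serum. For agreement of direction, 4 of 35 splits of the xenografts lay as far from 50% as the real 70.7%, the highest other being 77.4%, so chance was not excluded.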

How the results depend on the processing

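Counts of calls moved most. No called list turned in direction under the scalings, backgrounds and tests run for all lists, except MYC targets in cultures, higher under fry without a call (adjusted p 0.981). Planned before the data were examined were RLE factors, library totals, filters, limma-voom for genes, the replicate block, the pseudocount, the fold change, the digit in library names as a covariate, other-cell lists left out, an estimated correlation, fry, TMM factors for the difference between settings, agreement on genes called in cultures only, and single libraries left out. The others were chosen after the results were seen. In cultures the 1004 genes became 121 with no filter, 283 with coding genes only, 42 with coding genes corrected for GC content and length, 635 with a fold change of at least 1.5 (a stricter threshold) and 0 with transcripts not summed (50392 tested). They were 272 to 1678 with 1 library left out, 744 with RLE factors and 954 with limma-voom. The 24 lists became 11 with coding genes only, 4 after GC and length correction, and 0 both with an estimated correlation and with fry, and were 16 to 28 with 1 library left out. In xenografts the 0 genes became 5 with the mitochondrial share as a covariate (CHCHD2, DDT, H2AFZ, POLE4 and SEC61G, lower) and were 0 to 1 with 1 library left out. The 17 lists became 0 with an estimated correlation and 0 with fry, and were 11 to 22 with 1 library left out. The 13 genes that differed between settings became 8 with RLE factors (6 up, 2 down), 7 with TMM factors (5 up, 2 down) 1 with a t distribution and 0 in 1 limma fit of all 4 groups, and were 2 to 44 with 1 library left out. Agreement of direction was 60.5% to 73.9% with 1 xenograft library left out. Except where a reason is given, the cause was not tested. Over 77 named culture genes in 17 settings, 1018 of 1269 values kept their side of the threshold, 203 lost a call, 37 gained one, 11 uncalled values moved and 0 reversed. Over 61 xenograft genes in 24 settings, 1437 of 1447 kept their side and 10 moved. Since no xenograft gene was called in the main fit, none could lose a call. Library totals repeat the main fit, so their values could not move and add only kept values to both tallies. Of 38 called named culture genes, 6 kept their call with no filter, 9 of the 33 tested after GC and length correction, and with 1 library left out 14 to 18 did in 5 of 6 fits and 36 in the other. Changes of 2-fold were mostly not called in the simulated xenografts, and could have been missed in the real ones. A quasi-Poisson test on the whole reads of the xenografts called 0 genes. DESeq2 and edgeR were not run, since neither table holds counts as deposited, and the agreement of genes called in xenografts only has no value, with 0 called.

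With the replicate number as a block, cultures gave 1422 genes and 24 lists, and xenografts 0 genes and 20 lists. The labels do not pair the numbers, and not every sample correlated best with its own number: 1 of 3 culture pairs and 2 of 4 xenograft pairs did, with correlations of deviations from 0.155 to −0.119 and from 0.652 to −0.358.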

Other observations

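In Lac library 1 of the xenografts, INS, GCG and KRASP1 were at 0, and in the other 7 libraries they kept a narrow ratio to KRAS. Per 1000 CPM of KRAS, INS stood at 1.42 to 2.79, GCG at 1.46 to 3.52 and the pseudogene KRASP1, whose reads cannot be told from those of KRAS, at 0.860 to 1.16. ALAS2 stood at 1.37 to 5.51 over all 8. The pancreatic hormone PPY was at 0 in all 8 libraries, and SST reached 6.07 CPM.

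In cultures, ribosomal RNA took 3.54% to 5.27% of reads in NL and 2.83% to 3.46% in Lac libraries, and the 7SK and 7SL RNAs 8.70% to 10.0% and 7.87% to 8.57%. How such shares arose in libraries that the labels describe as poly(A) RNA was not tested. Both shares were lower in every Lac library than in any NL library. A preparation batch that follows serum, as depth does, cannot be told apart from serum for them. Each interval is within 0.0306 percentage points.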
